A study of Homo sapiens with 4 samples.

How the data were processed

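Gene expression was measured in HCC827 cells, an established human lung adenocarcinoma line, on 1-colour Agilent expression arrays. The 4 samples form 2 groups of 2 biological replicates, a non-targeting control and a METTL3 knockdown, taken from the labels of each sample. Cells were collected 12 days after infection with shRNA lentivirus and had been grown in medium with 10% serum, per the labels' protocols. Cy3-labelled complementary RNA was made from 0.2 µg of total RNA, per the labels' protocols. The labels give neither the shRNA sequence nor an exposure of these samples to osimertinib.

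The authors deposited 1 scanner file per array, whose spot intensity values were made with Agilent Feature Extraction 11.0.1.1, per the submitters' processing notes. Its processed signal is a linear intensity, background-subtracted and detrended within the array, per the file headers, and not scaled between arrays. The median spot and local background intensity columns that were used for a background alternative are uncorrected pixel medians, per the file headers. The flags for background, saturation and outliers are 0 or 1 marks of the scanner software, per the file headers. A table of processed values that the authors deposited for the whole series holds linear intensity for 21407 probes. Its scale was found by dividing the scanner's processed signal by it. The ratio was constant within 1% for 99.3% to 99.5% of probes on each array and lay at 490.1, 386.9, 337.9 and 269.5 for control replicates 1 and 2 and knockdown replicates 1 and 2. Those factors lay close to the 75th percentile over probes of each array, at 490.3, 387.5, 338.6 and 270.0. The table's columns had medians of 0.418, 0.414, 0.424 and 0.418, were not centred per gene, and were used only as an alternative. How the authors chose the probes they listed is not given in the sources used here.

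Each array carried 44495 spots, of which 43118 were not controls and measured 34127 probes, and 999 probes had 10 spots each. The main values were log2 of the processed signal minus the array's 75th percentile over non-control spots. Spots with an outlier flag, 0.68% to 0.88% per array, were left out unless all spots of a probe were flagged, and spots of a probe were averaged. A probe was kept when it was well above background on both arrays of at least 1 group, and a probe with several spots counted as such when at least 0.5 of them were. This left 20938 probes. Probe names were set through the RefSeq accession in the scanner files and a table of RefSeq genes of assembly GRCh38.p14. The array's own annotation was made on hg19, per the file headers, so no coordinates are printed. Of 27134 probes with a RefSeq accession, 25771 matched a symbol, which is 75.5% of all non-control probes, and 8356 probes stayed unnamed. Of the 19740 genes on the array, 13739 had a kept probe and were tested. Each was represented by its kept probe with the highest mean over the 4 arrays. Of 3225 genes with several tested probes, 66 had probes whose fold changes differed by over 1 on the log2 scale.

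Depth on an array is its signal over background. The share of probes well above background was 63.7% and 61.5% in the controls and 61.0% and 59.7% in the knockdown, and 0 spots were saturated. With 4 arrays, their number limits the precision. A probe well above background on neither array of a group has only a bound there. For such a gene "at least N-fold" is given, from the bright group's mean against the dim group's mean of, per array, the higher of the lowest signal among probes well above background and the gene's own signal. All 4 arrays lay on 1 slide and shared 1 scan, with the controls in positions 1 and 2 and the knockdown in positions 3 and 4. Position and group therefore cannot be told apart, and no fit with slide or scan as a block could be made.

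Groups were compared in R 4.3.3 with limma 3.58.1, using lmFit and eBayes on all 4 arrays with the group as the only term and Benjamini-Hochberg adjusted p with a threshold of 0.05. The fit had 2 residual degrees of freedom plus 3.57 from the prior. All tests were two-sided. An exact permutation test of 2 against 2 arrays cannot give a p below 0.333, so none is reported. Before the data were examined, 36 gene lists were fixed, with 591 genes in all, for pathways, complexes and cell types that the cells or the treatment could involve. The 34 lists with at least 3 tested members were compared with the remaining genes by limma's camera with a preset correlation between genes of 0.01. Camera with an estimated correlation and fry, limma's self-contained test, were run beside it. With an estimated correlation camera has only the 2 residual degrees of freedom, so a list could hardly pass after adjustment over 34 lists. The estimated correlation was far above the preset 0.01 for the 4 lists that passed with the preset. It was 0.298 for interferon-stimulated and 0.57 for ribosomal protein genes, 0.832 for replication and 0.909 for recombination genes. Members varying together may therefore alone account for a call lost there. Its share against that of the few degrees of freedom was not tested, and the estimates rest on the same 2. The lists of endothelial and neuroendocrine markers had too few measured members to be tested.

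Genes to be named were set by a rule fixed at the same time. METTL3, CDC25A and AURKB were always named. The 12 largest rises and 12 largest falls past the adjusted threshold were to be named if both knockdown arrays lay on the same side of both control arrays, the gene was well above background on all 4 arrays and unsaturated, and its name was a gene symbol. So were up to 3 genes per direction measured in only 1 group. From each list up to 4 members past the test were to be named, or, if fewer than 2 passed, the 2 with the greatest absolute change, with values only. Lists whose members did not move could be left out with counts. The values of 2 list members that the rule names are not reported here. No gene passed the threshold, so the rule named no gene beyond the fixed 3 and the list members. In addition, 24 genes, METTL3 among them, and 6 genes measured in 1 group only were chosen after their values were seen. The same rule was used, with an unadjusted p below 0.01 in place of the adjusted threshold.

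The fit was tested on simulated data with the spread of these arrays, in 20 simulations of the 13739 genes with 200 changed. It called 16.1% of genes changed 2-fold, 90.1% of those changed 4-fold, 97.4% of those changed 8-fold and 0.0528% of unchanged genes. The 200 changed genes were split evenly over 2-, 4-, 8- and 16-fold changes. So many large changes make the adjusted threshold easier to reach than in these data, where PTGFR, 4.84-fold higher, had a limma adjusted p of 0.248. These shares therefore do not show that a count of 0 genes excludes 4-fold changes. In 100 simulations of lists of 25 independent genes, camera gave an unadjusted p below 0.05 for 3% of unshifted lists and 100% of lists shifted by 0.5 on the log2 scale. Real list members vary together, which these simulations leave out.

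Alternatives set in advance were normexp background correction with an offset of 50, quantile normalization, centring on the median, no filter on dim probes, a filter on all 4 arrays, the mean of a gene's probes, outlier spots kept, an intensity trend with a robust prior, the authors' deposited intensity table, the replicate number as a block, and each array left out in turn. The normexp step used the median spot signal, because the mean spot signal is not among the columns used here. Cyclic loess, scaling on 7 bright spike-in probes and a fit over all probes without the gene step were added after the data were seen.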

Results

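Messenger RNA levels were compared between HCC827 cells with a METTL3 knockdown and cells with a non-targeting control. METTL3 is the catalytic subunit of the methyltransferase that places N6-methyladenosine on messenger RNA. HCC827 is a lung adenocarcinoma line that depends on mutant EGFR, the kinase inhibited by osimertinib. The series title asks about osimertinib resistance and names CDC25A and AURKB as regulated by METTL3. Each group held 2 biological replicates, all collected 12 days after infection. The 75th percentile of the processed signal was 726.5 and 568.8 in control replicates 1 and 2 and 505.2 and 400.1 in knockdown replicates 1 and 2. Between 59.7% and 63.7% of probes were well above background. Pearson correlations across genes, which are not independent replicates, ran from 0.9813 between control 1 and knockdown 2 to 0.9919 between the controls.

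METTL3 messenger RNA was 2.77-fold lower in the knockdown, with a log2 fold change of -1.47 (SE 0.17, 95% interval -1.90 to -1.04, n = 2 per group). Its log2 level relative to the array's 75th percentile was 1.30 ± 0.14 in the controls and -0.17 ± 0.17 in the knockdown (SD, n = 2). Both knockdown arrays, at -0.29 and -0.05, lay below both controls, at 1.40 and 1.20. The gene was read by 1 probe, A_33_P3449397, above background on all 4 arrays. It ranked 6 of 13739 genes by p, but its limma adjusted p was 0.248, and it therefore did not pass over all genes. Scaled on spike-in probes, an alternative chosen after the data were seen, METTL3 passed at a log2 fold change of -1.89, but this scaling lowers every gene alike and limma's prior degrees of freedom became infinite there, against 3.57.

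CDC25A, the phosphatase that activates cyclin-dependent kinases at entry into and during S phase, was 2.01-fold lower in the knockdown. Its log2 fold change was -1.01 (SE 0.22, 95% interval -1.55 to -0.46, n = 2 per group), from 0.39 ± 0.03 to -0.62 ± 0.38 (SD, n = 2). AURKB, the mitotic kinase Aurora B, had a log2 fold change of -0.60 (SE 0.48, 95% interval -1.80 to 0.60, n = 2 per group). Its 2 knockdown arrays differed widely, at 0.91 in replicate 1 and -0.43 in replicate 2, against 1.21 and 0.46 in the controls. Knockdown replicate 1 thus lay between the controls for AURKB, while both knockdown arrays lay below both controls for CDC25A. Each gene was read by 1 probe, A_24_P397107 for CDC25A and A_23_P130182 for AURKB. The limma adjusted p was 0.281 for CDC25A and 0.584 for AURKB, so neither passed. Both genes stand in the series title and were possibly chosen on these samples, so their direction is not independent evidence. Without knockdown replicate 2 the AURKB log2 fold change turned to 0.07, and with spike-in scaling, under the same infinite prior, CDC25A passed at -1.43.

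**Figure D1:**
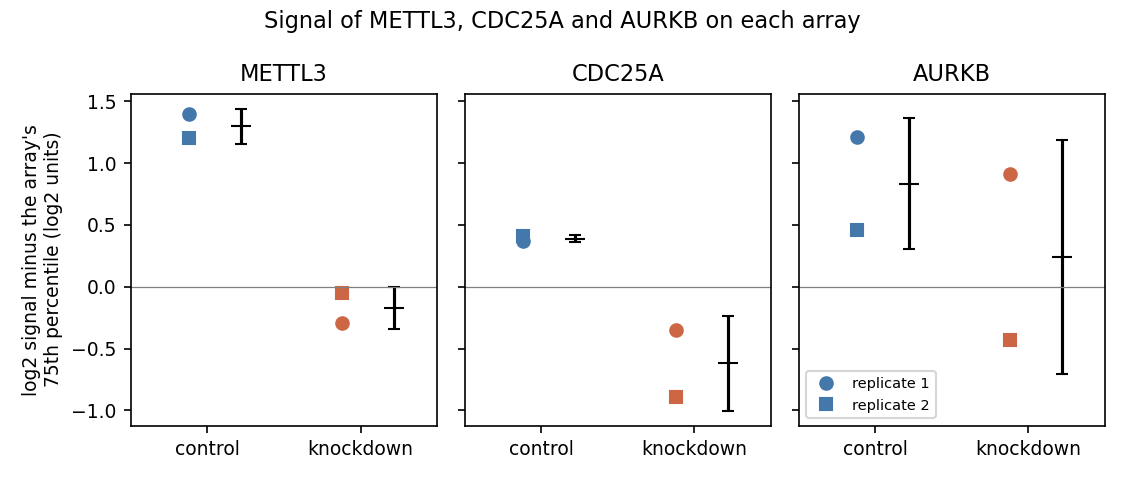
Signal of METTL3, CDC25A and AURKB on each array, as log2 processed signal minus the array's 75th percentile (y axis, log2 units), with controls in blue and knockdown in orange, circles for replicate 1, squares for replicate 2, and black marks for the mean ± SD (n = 2). METTL3 and CDC25A were lower on both knockdown arrays than on both controls, whereas AURKB was 0.91 in knockdown replicate 1, between the controls at 1.21 and 0.46.

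Across the transcriptome, 169 genes measured at least 2-fold higher and 81 at least 2-fold lower in the knockdown, and for 159 and 71 of them the groups did not overlap. No single gene passed the adjusted threshold, with 0 of 13739 in limma and a smallest adjusted p of 0.248. At an unadjusted p below 0.05 there were 1819 genes, 1102 higher and 717 lower, where chance gives about 687. Groups did not overlap for 29.1% of genes in the upward and 20.2% in the downward direction, against 16.7% each by chance. Of 3384 unnamed probes, 0 passed in limma and 432 had an unadjusted p below 0.05. The count of 0 rose to 6 without control replicate 1, 13 without control replicate 2, 40 without knockdown replicate 1 and 21 without knockdown replicate 2. It rose to 420, 41 higher and 379 lower, when arrays were scaled on spike-in probes, which moved the median log2 fold change of all genes from 0.05 to -0.37 and made limma's prior degrees of freedom infinite, against 3.57.

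The next 24 genes, 12 per direction, had the greatest fold changes at an unadjusted p below 0.01 among genes that met the naming filters. Those filters required groups that did not overlap, signal well above background on all 4 arrays, no saturation and a gene symbol. The genes were chosen after their values were seen, and none passed the adjusted threshold (limma adjusted p 0.248 to 0.295). NPPB, the precursor of B-type natriuretic peptide, measured 2.64 higher on the log2 scale (SE 0.53), complement C3 2.00 (SE 0.46), the fibrinogen chain FGA 2.21 (SE 0.29), the metalloprotease ADAMTS10 2.07 (SE 0.41) and the collagen COL5A1 1.82 (SE 0.40). The prostaglandin F receptor PTGFR measured 2.28 higher (SE 0.22), the alveolar phosphate transporter SLC34A2 2.06 (SE 0.34), the teneurin TENM2 2.00 (SE 0.32) and the activin-receptor-like kinase ACVRL1 1.77 (SE 0.31). ODAPH, the cadherin FAT4 and the endocytic adaptor DAB2 had log2 fold changes of 1.81, 1.63 and 1.61. On the lower side stood the cytokine IL37 at -1.70 (SE 0.36), bleomycin hydrolase BLMH at -1.51 (SE 0.20) and smooth muscle actin ACTG2 at -1.45 (SE 0.24). The ubiquitin-pathway genes UBE2E1 and UBR3 were at -1.39 and -1.36, the lipid transporter MFSD2A at -1.39 and the growth factor FGF9 at -1.36. SNORA62, a small nucleolar RNA hosted in another gene, was at -1.35, the prostaglandin E receptor PTGER4 at -1.31, FAM91A1 at -1.30 and the matrix protein THBS2 at -1.25. METTL3 was the remaining gene of the 24. Without control replicate 2 the value of C3 was 1.28. With normexp, which also used the median spot signal, the 12 higher genes ran from 0.91 for ODAPH to 1.59 for C3. Of the lower genes, MFSD2A then stood at -0.08, UBE2E1 at -0.11, UBR3 at -0.24, ACTG2 at -0.27, THBS2 at -0.29, FAM91A1 at -0.59, FGF9 at -0.62, IL37 at -1.03 and BLMH at -1.08.

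Some genes were well above background in 1 group only, again chosen after their values were seen. IL1RL1, the receptor for interleukin-33, was at least 4.38-fold lower in the knockdown (limma adjusted p 0.257). FBN2, a fibrillin of elastic microfibrils, was at least 4.32-fold lower (limma adjusted p 0.248). CCNYL1 was at least 2.05-fold lower, but its log2 fold change turned from -1.28 to 0.16 with normexp background correction. The lymphotoxin LTB was at least 3.02-fold higher, the receptor KLRC4 at least 2.67-fold higher and REG1A at least 2.52-fold higher. These bounds hold for the processed signal only, since with normexp the log2 fold changes were -0.29 for IL1RL1, -0.20 for FBN2, 0.64 for LTB, 0.65 for KLRC4 and 0.54 for REG1A.

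Interferon-stimulated genes, which are switched on by antiviral signalling, were higher in the knockdown. Of 25 measured members, 23 were higher and 2 lower, with a mean log2 fold change of 0.50, and for 15 of them both knockdown arrays lay above both controls, against 16.7% of genes by chance and 29.1% of all tested genes. IFI6 measured 1.55 higher (SE 0.19) and CMPK2 0.86 (SE 0.18), and both rose when adjusted over the list alone, at adjusted p 0.00738 and 0.0485, while with normexp CMPK2 stood at 0.56. IFI44L at 0.96 (SE 0.23) and IFIT1 at 0.88 (SE 0.23), named after their values were seen, did not pass. Over all genes tested 0 members passed in limma, against 2 adjusted over the list alone and 9 at an unadjusted p below 0.05. The list passed limma's camera (adjusted p = 7.23e-05 over 34 lists), but not with an estimated correlation (adjusted p = 0.856, unadjusted p = 0.205). Without control replicate 2 the list stood 0.29 above all genes, against 0.45 with all arrays, and still passed. The mean per array, relative to each gene's own mean, was -0.11 and -0.39 in the controls and 0.13 and 0.37 in the knockdown, so that the gap between control 1 and knockdown 1 was about as wide as the gap within either group.

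Genes of DNA replication and homologous recombination were lower in the knockdown. Of 38 replication genes 34 were lower, with a mean log2 fold change of -0.24. The clamp loader subunit RFC3 was at -0.53 (SE 0.26) and the flap endonuclease FEN1 at -0.52 (SE 0.40). Of 15 recombination genes 13 were lower, with a mean of -0.31, and among them BRCA2 was at -0.82 (SE 0.30) and the checkpoint kinase CHEK1 at -0.63 (SE 0.23). In limma 0 members of either list passed over all genes or adjusted over the list alone, and 1 replication and 2 recombination genes were lower at an unadjusted p below 0.05. Groups did not overlap for 11 replication and 5 recombination genes in the lower direction, against 16.7% by chance and 20.2% of all tested genes. Knockdown replicate 2 stood apart, with a mean of -0.41 for both lists together relative to each gene's own mean, against 0.21 and 0.05 in the controls and 0.15 in knockdown replicate 1. Camera's adjusted p was 2e-04 for replication and 0.012 for recombination, and both were lost with an estimated correlation (adjusted p = 0.856 for each, unadjusted p = 0.458 and 0.451). Without knockdown replicate 2 the replication list stood only -0.01 and the recombination list -0.03 from all genes, against -0.29 and -0.36 with all arrays, and FEN1 turned to 0.09. The recombination list also lost its call without control replicate 1, at -0.22, and with cyclic loess, at -0.34, and with normexp BRCA2 stood at -0.09 and FEN1 at -0.21.

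Mitotic genes, a list that includes kinases and kinetochore proteins, had a mean log2 fold change of -0.15 with 27 of 34 members lower. The groups overlapped for each member, and in limma 0 passed over all genes, adjusted over the list alone or at an unadjusted p below 0.05. The list did not pass camera (adjusted p = 0.098, and adjusted p = 0.856 with an estimated correlation). CDK1 was at -0.66 (SE 0.34) and the centromeric histone CENPA at -0.58 (SE 0.34). The list passed downward without control replicate 2 or knockdown replicate 1, with normexp, without the filter on dim probes, with the replicate number as a block and with spike-in scaling. Its direction rested on knockdown replicate 2, without which the list passed upward, 0.23 above all genes.

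**Figure D2:**
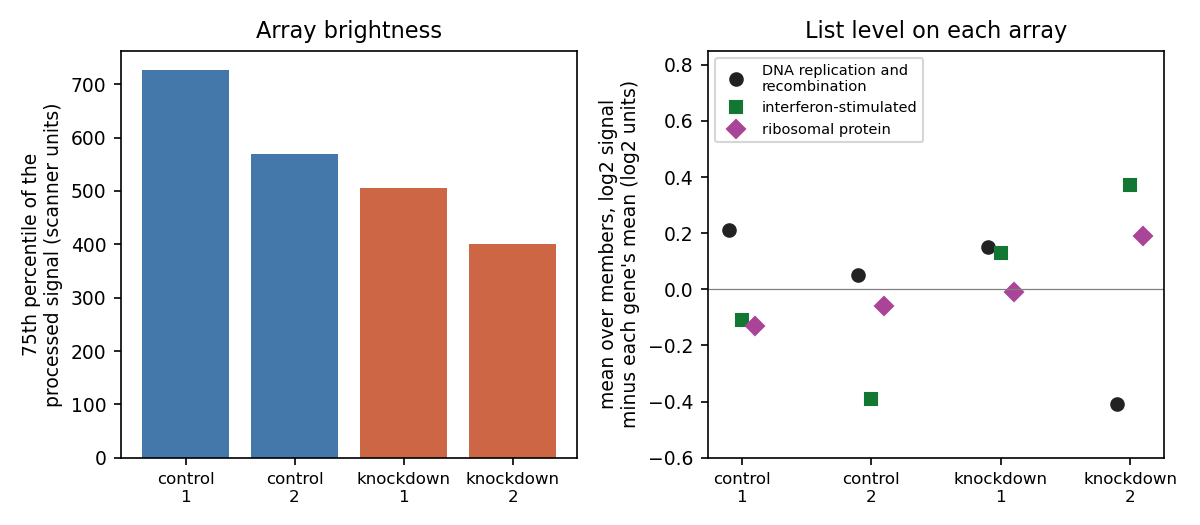
Left, 75th percentile of the processed signal on each array (bars, scanner units; controls blue, knockdown orange), from 726.5 in control replicate 1 to 400.1 in knockdown replicate 2. Right, mean level of 3 groups of genes on each array (points, log2 signal minus each gene's mean over the arrays), where replication and recombination genes were at -0.41 in knockdown replicate 2 and at 0.05 to 0.21 on the other arrays.

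Ribosomal protein genes were slightly higher in the knockdown, with a mean log2 fold change of 0.19. Of 40 members 34 were higher, and for 24 of them the groups did not overlap, against 16.7% by chance and 29.1% of all tested genes. The mean per array, relative to each gene's own mean, was -0.13 and -0.06 in the controls and -0.01 and 0.19 in the knockdown. RPS4X was at 0.35 (SE 0.16) and RPLP2 at 0.34 (SE 0.18), and with spike-in scaling, which lowers every gene alike, their values turned to -0.07 and -0.08 by construction. In limma 0 members passed over all genes, adjusted over the list alone or at an unadjusted p below 0.05. The list passed camera (adjusted p = 0.012), but not with an estimated correlation (adjusted p = 0.856, unadjusted p = 0.516). Its distance from all genes shrank from 0.14 to 0.02 with normexp, 0.03 with quantile normalization, 0.01 with cyclic loess, 0.01 with no filter on dim probes and 0.06 without knockdown replicate 2. The call was also lost with spike-in scaling, at 0.14, and without control replicate 1, at 0.12, or 2, at 0.15.

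**Figure D3:**
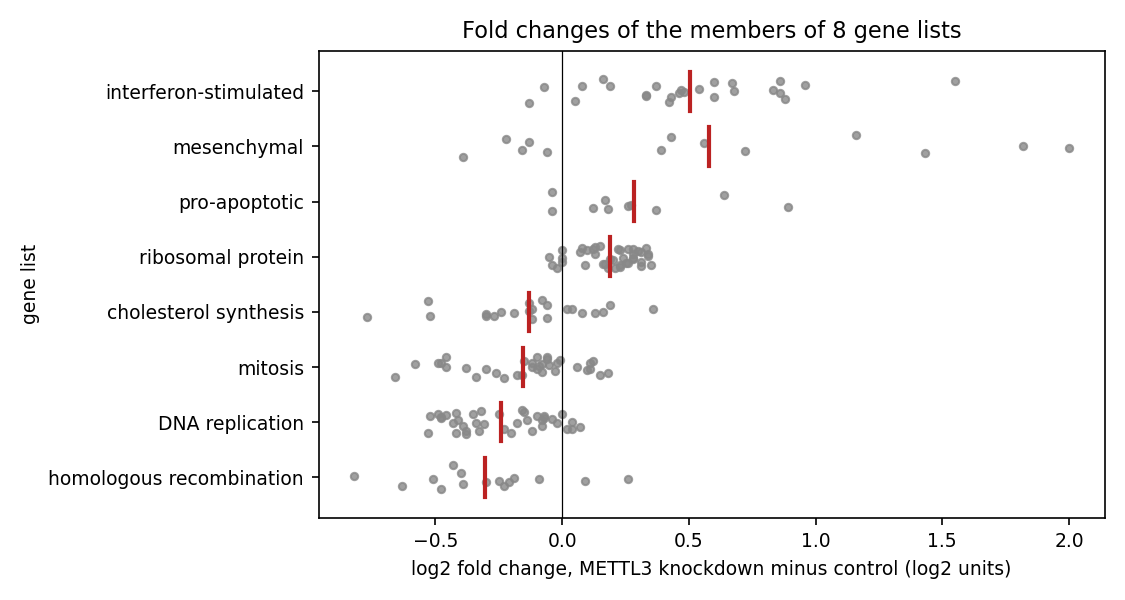
Log2 fold change of each tested member of 8 gene lists (x axis, METTL3 knockdown minus control, log2 units; points are genes, red bars the list means). The mean was 0.50 for interferon-stimulated, 0.19 for ribosomal protein (RPS4X and RPLP2 turned negative with spike-in scaling, which lowers every gene alike), -0.24 for DNA replication and -0.31 for homologous recombination genes.

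Mesenchymal markers had a mean log2 fold change of 0.58 with 8 of 13 members higher and 5 lower. Adjusted over the list alone 4 members rose, against 0 over all genes in limma and 4 at an unadjusted p below 0.05. COL5A1 measured 1.82 higher (SE 0.40), the transcription factor ZEB1, a repressor of epithelial genes, 1.43 (SE 0.21), and the matrix protein SPARC 1.16 (SE 0.19). The list as a whole did not pass camera (adjusted p = 0.098, and adjusted p = 0.856 with an estimated correlation). It passed without any 1 of the 4 arrays, with normexp and with spike-in scaling, each in the upward direction, and with normexp COL5A1 stood at 1.00 and SPARC at 0.59. Without knockdown replicate 1 COL5A1 stood at 1.21.

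Pro-apoptotic genes had a mean log2 fold change of 0.28 with 8 of 10 members higher, and for 7 the groups did not overlap, against 16.7% by chance and 29.1% of all tested genes. BMF, a BH3-only protein, measured 0.89 higher (SE 0.21) and BAK1, a pore-forming effector of the mitochondrial pathway, 0.64 (SE 0.17). Both rose when adjusted over the list alone, at adjusted p 0.0483 each, against 0 over all genes in limma and 2 at an unadjusted p below 0.05. Cholesterol synthesis genes had a mean of -0.13 with 15 of 22 lower, among them the sterol carrier STARD4 at -0.77 (SE 0.26) and INSIG1 at -0.53 (SE 0.29). Neither list passed camera (adjusted p = 0.098 each, and adjusted p = 0.856 each with an estimated correlation). The cholesterol list passed downward with normexp, without the filter on dim probes, without control replicate 1 and without knockdown replicate 2.

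Lists of signalling outputs, ligands and receptor kinases related to EGFR signalling did not pass. Readouts of MAPK signalling had a mean log2 fold change of -0.20 with 13 of 18 lower (camera adjusted p = 0.113), and EGR1 was at -0.91 (SE 0.64) and the phosphatase DUSP5 at -0.73 (SE 0.38). Immediate early genes had a mean of -0.37 with 7 of 12 lower (camera adjusted p = 0.225), and FOSB was at -2.00 (SE 0.93). The control replicates themselves lay far apart for FOSB, at -1.88 and -4.79, and for EGR1, at 3.30 and 1.26. The FOSB knockdown mean was -5.34, so the size of its fall rested largely on control replicate 1. Without that array EGR1 turned to 0.11. Ligands of ERBB and of other receptor kinases had 4 of 10 members higher, with a mean of 0.07 but a median of -0.09 and a downward direction in camera. Among them GAS6, the ligand of AXL-family kinases, was at 1.27 (SE 0.48) and HBEGF at -0.89 (SE 0.47). Among receptor kinases 9 of 14 were higher, with FGFR3 at 0.76 (SE 0.22) and MERTK at -0.63 (SE 0.16). Camera's adjusted p was 0.709 for the ligands and 0.676 for the receptors, and in limma 0 members of these 4 lists passed over all genes or adjusted over the list alone. At an unadjusted p below 0.05, 1 MAPK gene was higher, 2 immediate early genes were lower, 1 ligand was higher, and 1 receptor was higher and 1 lower. The MAPK list passed downward without control replicate 2, without knockdown replicate 1, with normexp, without the filter on dim probes and with spike-in scaling. The immediate early list passed downward without control replicate 2, without knockdown replicate 2, with normexp and with spike-in scaling, and with normexp FOSB stood at -0.53, DUSP5 at -0.38, GAS6 at 0.63 and MERTK at -0.08.

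The remaining measured members of the methyltransferase complex showed no change that passed in limma with the reported settings. Of 7 measured writers other than METTL3, 4 were higher and 3 lower, with a mean log2 fold change of -0.02, and 1 more listed writer was not tested. The groups did not overlap for 2 in the upward direction and for 1, WTAP, in the downward direction, against 29.1% and 20.2% of all tested genes. WTAP was at -0.42 (SE 0.23) and METTL16, a separate methyltransferase, at 0.26 (SE 0.15). Readers and erasers had a mean of 0.08 with 9 of 14 higher, and among them the demethylase FTO was at 0.39 (SE 0.21) and IGF2BP1 at 0.36 (SE 0.15). With spike-in scaling METTL16, FTO and IGF2BP1 turned to -0.16, -0.03 and -0.07 by construction, as that scaling lowers every gene alike. Camera's adjusted p was 0.801 for writers and 0.709 for readers and erasers, and in limma 0 members passed over all genes, adjusted over the list alone or at an unadjusted p below 0.05.

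Across all fixed lists, 4 of 34 passed camera with the preset correlation, 2 upward and 2 downward, while 0 passed with an estimated correlation and 0 by fry's directional test, whose smallest adjusted p was 0.471. Fry's mixed test, which asks whether members change in either direction, passed for 2 lists, targets of NRF2 and fibroblast markers (adjusted p = 0.0423 each).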

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

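The spike-in comparison, the test of probe brightness on ribosomal protein genes and the reading of the tests of a brightness gradient as open were chosen only after the result was seen, and the other tests were chosen once the list shifts were known but before their own values were seen.

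The spike-in probes, which enter no test reported above except through the alternative scaling on them, differed between the groups. Relative to the array's 75th percentile, the 7 bright ones had a mean log2 level of 0.23 ± 0.14 in the controls and 0.66 ± 0.26 in the knockdown (SD, n = 2), a difference of 0.43. Whether equal amounts of spike-in were added to each sample is not given in the sources used here, so neither this difference nor the genes called under spike-in scaling can be read as a change in RNA content. The log2 level of the spike-in probes themselves differed by -0.09, while the 75th percentile differed by -0.52. The values per array were 0.33, 0.13, 0.47 and 0.84 for control replicates 1 and 2 and knockdown replicates 1 and 2.

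The first pattern weighed is the higher level of interferon-stimulated genes in the knockdown. A fold change that depends on probe brightness was argued against, since the list's mean of 0.50 lay at percentile 100 of 10000 random lists matched on signal, whose central 95% ran from -0.09 to 0.18. A single array alone was argued against, as at least 0.37 was left without any 1 of the 4 arrays. A gradient that follows array brightness stays open, since the difference of replicate 2 and replicate 1 over the knockdown shift, -0.03 where brightness gave 0.67, averages -0.28 in the controls and 0.24 in the knockdown, so the bound set for it decides nothing. An effect of METTL3 loss, a response to the shRNA itself and position on the slide stay open and were not tested, and the list also passed upward for control 1 and knockdown 2 against the other arrays.

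The second pattern is the lower level of DNA replication and recombination genes, 53 genes with a mean of -0.26. Probe brightness was argued against, since that mean lay at percentile 0 of matched random lists, whose central 95% ran from -0.04 to 0.13. A gradient that follows array brightness was neither excluded nor met, since the difference of replicate 2 and replicate 1 was 1.38 times the knockdown shift (95% bootstrap interval over genes, which vary together, 1.15 to 1.68), above the 0.67 of brightness, and knockdown 1 stood above the brighter control 2. A single array could account for it, as the mean was 0.02 without knockdown replicate 2, whose level of -0.41 stood apart from 0.21, 0.05 and 0.15 on the other arrays. Both other splits of the 4 arrays called these lists downward on the side that held knockdown 2, so a state of that culture, such as its growth at harvest, may account for it, as may METTL3 loss, and neither was tested.

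The third pattern is the higher level of ribosomal protein genes. Probe brightness remains possible, since the list's mean of 0.19 lay at percentile 78 of matched random lists, which averaged 0.17. Those lists were drawn from all tested genes, members of this list included, which pulls their average towards 0.19 by an amount that was not measured. A gradient that follows array brightness remains possible as well, with a ratio of 0.73 (95% bootstrap interval over genes 0.57 to 0.92) beside 0.67 for brightness. Dependence on a single array met the bound set for it, though narrowly, with 0.09 left of 0.19 without knockdown replicate 2, so a single array could account for it. No biological explanation was tested for this pattern.

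The 4 arrays form only 3 splits of 2 against 2, too few for a share under 0.05. The real split called 4 lists and 1819 genes at an unadjusted p below 0.05, and limma called 0 genes in each split. The highest other values were 8 lists, reached by both other splits, and 784 genes, for control 2 and knockdown 2 against the other arrays.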

How the results depend on the processing

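Cyclic loess, spike-in scaling and the fit over all probes were tests chosen only after the data were seen, and the others were planned. List values are the list mean minus the mean of all genes, with all arrays 0.45 for interferon-stimulated, -0.29 for DNA replication, -0.36 for homologous recombination and 0.14 for ribosomal protein genes. The cause was not tested for any change given here unless stated. The median in place of the 75th percentile, the filter on all 4 arrays, the mean of a gene's probes, outlier spots kept, the intensity trend with robust prior and the authors' table kept the count of 0 genes, the 4 list calls and the directions of METTL3, CDC25A and AURKB. Over all alternatives the log2 fold change ran from -1.89 to -1.35 for METTL3 (adjusted p 1.03e-05 to 0.353), -1.43 to -0.74 for CDC25A (0.00307 to 0.541) and -1.27 to 0.07 for AURKB (0.0637 to 0.999). Of 19 settings, the reported one included, interferon-stimulated genes passed in 17, DNA replication in 16, homologous recombination in 14 and ribosomal protein genes in 9. With normexp 13 lists passed, ribosomal proteins stood at 0.02, and CCNYL1, ME1 and FAP turned to 0.16, 0.13 and 0.32. This alternative changes both the signal column and the offset, which were not tested apart. Quantile normalization put ribosomal proteins at 0.03 and no filter on dim probes at 0.01, with 9 lists passing in the latter. With the replicate number as a block, which the labels do not establish as a pairing, 1 gene passed and changed at least 2-fold, CAPSL at 2.89, named after its value was seen, and deviations of arrays with the same number correlated at 0.40 across genes, which are not independent replicates. With an estimated correlation and with fry's directional test 0 lists passed at the same 0.45, -0.29, -0.36 and 0.14, since these tests change only the p. Cyclic loess left 2 lists, with recombination at -0.34 and ribosomal proteins at 0.01. Spike-in scaling subtracts 1 offset per array from every gene, so that genes are not independent and sign changes of small values follow by construction, made limma's prior degrees of freedom infinite, and gave 420 genes, each at least 2-fold, METTL3 at -1.89, CDC25A at -1.43, 8 lists, ribosomal proteins no longer passing at 0.14, and FTO, IGF2BP1, METTL16, RPS4X and RPLP2 at -0.03, -0.07, -0.16, -0.07 and -0.08. Without each array in turn, where the lone array is assumed to vary like the others, 6 to 40 genes passed, each at least 2-fold, 74 in all with 5 called at least 2 times, and 5 to 9 lists. Values then ran from -1.27 to 0.07 for AURKB, -1.93 to 0.11 for EGR1, -1.12 to 0.09 for FEN1, 0.29 to 0.62 for interferon-stimulated genes, -0.57 to -0.01 for replication, -0.68 to -0.03 for recombination, 0.06 to 0.22 for ribosomal protein and -0.64 to 0.23 for mitotic genes. Over all probes without the gene step limma called 0 of 20938, with 2804 at an unadjusted p below 0.05, and lists were not run. Other comparisons of named genes kept direction and side of the threshold in 1124 cases and newly passed in 63, and for lists not called in 498 and 40. No slide or scan block was run, as all arrays share 1 slide. Signal over background limits what could be tested, with 59.7% to 63.7% of probes well above it.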

Other observations

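Tests of probe brightness and gene length given here were chosen only after the result was seen.

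Targets of NRF2, the regulator of the oxidative stress response, went both ways, with 5 of 17 members higher and 12 lower, a mean log2 fold change of -0.06 and a median of -0.18, and passed fry's mixed test for change in either direction (adjusted p = 0.0423). HMOX1, which degrades heme, measured 1.60 higher (SE 0.41) and the malic enzyme ME1 -0.73 (SE 0.15), and with normexp ME1 turned to 0.13. YAP targets had 7 members higher and 7 lower, a mean of -0.12 and a median of 0.03. NT5E, the ecto-enzyme that makes adenosine, was at -1.16 (SE 0.20) and fell when adjusted over the list alone (adjusted p = 0.021), and CCN2 was at -1.48 (SE 0.93). Antigen presentation genes had 11 of 13 members higher, with HLA-B at -0.48 (SE 0.16). Lung epithelial markers had 12 of 16 members higher, with the surfactant protein SFTPB at -1.07 (SE 0.29) and the club cell protein SCGB1A1 at 0.80 (SE 0.25). Camera's adjusted p was 0.113 for NRF2 targets, 0.577 for YAP targets, 0.295 for antigen presentation and 0.693 for lung epithelium, and adjusted p = 0.856 for each with an estimated correlation. In limma 0 of their members passed over all genes. The NRF2 list passed downward without the filter on dim probes and without knockdown replicate 2, and the YAP list downward without knockdown replicate 2. With normexp CCN2 stood at -0.69, and without control replicate 1 at -0.02.

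Markers of other cell types were mostly near background. Of 10 fibroblast markers 3 were measured. COL1A1 was at 1.31 (SE 0.16) and rose when adjusted over the list alone (limma adjusted p = 0.000749). FAP was at -0.48 (SE 0.31), but only 1 of its 2 knockdown arrays was well above background, so this value is uncertain. With normexp FAP turned to 0.32, COL1A1 stood at 0.78 and the list passed upward. The 3 markers passed fry's mixed test (adjusted p = 0.0423), though only 1 of them, COL1A1, had an unadjusted p below 0.05 in limma. Of 10 leukocyte markers 5 were measured, with CD14 at 0.62 (SE 0.27) and CD3D at 0.53 (SE 0.33). The brighter CD68 and CSF1R differed little, at -0.03 (SE 0.17) and 0.08 (SE 0.17). Camera's adjusted p was 0.328 for both lists, and adjusted p = 0.856 with an estimated correlation. Transcripts reported as METTL3 targets had 6 of 13 members higher and 7 lower, with a mean of -0.03 (camera adjusted p = 0.629). The remaining lists did not pass with the reported settings, with means from -0.45 for squamous and basal markers (camera adjusted p = 0.202) to 0.22 for efflux transporters (camera adjusted p = 0.276), and in limma 0 of their members passed over all genes. With normexp the lists of heat shock, oxidative phosphorylation, integrated stress and epithelial genes passed downward. Heat shock and integrated stress genes also did so without the filter on dim probes, and heat shock genes without knockdown replicate 2. Squamous and basal markers passed downward without control replicate 2, without knockdown replicate 2 and with spike-in scaling, and inflammatory targets of NF-kappaB upward without control replicate 1.

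The median log2 fold change depended on signal, at 0.11 in the dimmest of 10 equal groups of genes, -0.01 in group 5 and 0.12 in the brightest, and the median difference of replicate 2 and replicate 1 within groups was 0.08, 0 and 0.13 there. Across 13739 genes, which are not independent replicates, Spearman's rho with gene length was -0.10 for the knockdown and -0.11 for replicate 2 minus replicate 1. The median was 0.12 in the shortest 20% of genes and 0.04 in the longest 20%. The first principal component held 59.3% of the variance and placed the arrays at 0.71 and 0.14 for the controls and -0.18 and -0.67 for the knockdown. On this component alone, control 2 and knockdown 1 lay closer together than the replicates of either group. The order is also that of slide position and of array brightness, with log2 75th percentiles of 9.505, 9.152, 8.981 and 8.644. The first component therefore cannot be read as the knockdown alone. On the second, with 26.3% of the variance, control 2 and knockdown 1 lay furthest apart, at -0.61 and 0.75. Their Pearson correlation across genes was 0.9907, below 0.9919 between the controls and 0.9916 between the knockdown arrays.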
